A study of Danio rerio with 2 samples.

How the data were processed

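Hearts of zebrafish embryos of the AB background were taken at 48 hours post fertilization from wild-type and kctd10 mutant animals, per the labels. RNA was isolated on RNeasy columns and libraries were made with an Illumina TruSeq kit, per the labels' protocols. Each genotype has 1 library, and how many hearts each library pools is not given in the sources used here. The submitters' processing notes name TopHat, DESeq and the genome build Zv9 without versions. The counting tool, the annotation release, the use of strand and the treatment of reads with several matches are not given in the sources used here, so genes that overlap or share sequence with a copy are uncertain.

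The authors deposited raw counts per Ensembl gene for both libraries, whole numbers without normalization. The line of the table that names no gene held 9.21% of all counts in the library labelled wild type and 9.17% in the library labelled mutant, and stayed out of library sizes. The authors' deposited comparison of Ensembl genes gives a fold, its log2 value, a p-value and an adjusted p-value from DESeq, per the file headers. Its values show that the ratio of mutant to wild type was taken after dividing each library's counts by 1 size factor. A second comparison, on UniGene clusters, holds a fold and its log2 value, per the file headers, both given to 2 decimals. Its fold column carries the name OE over CON, while its first line speaks of the mutant against the wild type. Further columns of numbers in both comparisons, whose names match no label, were not used. The UniGene comparison holds 22734 clusters, 9594 without a symbol, and 7 symbols had been turned into dates.

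The columns of the count table are named with abbreviations of the genotypes and were assigned to the libraries on that basis. Library sizes were scaled by TMM with edgeR 4.0.16 in R 4.3.3, giving effective sizes of 148672835 and 140343348 counts. For each gene the ratio of the library labelled mutant over the library labelled wild type was computed with an exact 95% Clopper-Pearson interval from both counts. A gene with at least 10 counts over both libraries was called higher when the whole interval lay above 1.5-fold and lower when it lay below the inverse of 1.5. The log2 ratio used 0.5 added to each count. A gene at 0 in a library was given a fold against a floor of 3 counts in that library, 0.0202 and 0.0214 CPM in the libraries labelled wild type and mutant. The 14685 genes with at least 1000 counts had a median interval half-width of 0.07 on the log2 scale. No statistical test between genotypes was run, since each has 1 library.

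Before the data were examined, 31 gene lists, the calling rule, the rule for named genes and the alternatives below were fixed, except those said to be added later. Of these lists 2, and some genes the rule names, are not reported here. Symbols were matched to the names in the authors' comparison table and then to a current table of gene names. Of 991 list entries 907 (91.5%) matched, giving 858 genes, 32 of them in several lists. The authors' table gave 18290 identifiers a symbol, and the current table named 19540. The median log2 ratio of the measured members was given with an exact order-statistic interval and with its percentile among 10000 random lists, in which each member was replaced by a gene drawn from the 200 nearest in mean expression. A list stands apart below percentile 2.5 or above 97.5. Percentiles describe these libraries and test no hypothesis about genotypes. Named genes were kctd10, the 12 higher and 12 lower genes with a symbol and at least 50 counts whose interval bound lay farthest from no change, and for each list up to 2 higher and 2 lower members and the most counted one. Where a symbol had several identifiers, the one with the most counts stood for it. The genes nkx2.5, tbx5a, bmp4, has2, tnfaip1 and kctd13, and those named among the additional observations, were chosen after their values were seen. No genome or annotation of Zv9 was used, so no coordinates are given.

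The steps were tested on simulated counts for this pair of libraries, with 200 genes changed among 24002 measured genes. Of the genes raised 2-fold 70.0% were called higher and of those raised 4-fold 100%. Of the genes lowered to 0.5 and 0.25 of their level, 77.6% and 91.8% were called lower, and 5 unchanged genes were called. The intervals held the true ratio for 95.4% of genes. Of 248 random unchanged lists 1.61% stood apart. Both simulated libraries were drawn around a shared profile with counting noise alone, so the coverage and the few false calls follow from that design. They do not measure false calls between real libraries, which also differ in animals, dissection and amplification. The alternatives were DESeq2 1.42.0 size factors, library totals, upper-quartile factors, factors without the 100 most counted genes, other fold, count and interval limits, means in place of medians, and the authors' folds. Scaling to the median of the cardiac sarcomere list and the authors' folds for kctd10 were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.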

Results

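RNA was sequenced from hearts of zebrafish (Danio rerio, AB background) at 48 hours post fertilization, a stage at which the embryonic heart has formed its atrium, ventricle and the canal between them. The series holds 1 library from wild-type hearts and 1 from hearts of kctd10 homozygous mutants. kctd10 encodes an adaptor that brings substrates to the Cullin 3 ubiquitin ligase. The comparison asks which transcripts differ in amount between heart samples of both genotypes. The gene counts summed to 150001992 in the library labelled wild type and 139099775 in the library labelled mutant, over 26126 listed genes. The keratin gene krt4, a gene of the larval surface epithelium, took the most counts in both, with 3.0% and 2.14% of the total, while the cardiac myosin gene vmhc had 323839 and 455687 counts and the hatching enzyme gene he1a had 620428 and 553410. With 1 library per genotype no replicate check was possible, so every ratio below compares 2 libraries and not the genotypes, and no p-value was computed. The 95% intervals cover counting error only, and amplified reads without molecular identifiers are not independent molecules. Genes of tissues other than the heart were counted too, so these counts alone assign no ratio below to heart cells.

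The transcript of the mutated gene was more abundant in the library labelled mutant. kctd10 (ENSDARG00000017115) had 8226 counts in the library labelled wild type and 19942 in the library labelled mutant, a ratio of 2.57 (95% counting interval 2.5 to 2.64). The direction is opposite to a loss of the transcript. A sequence mutation need not lower the amount of its messenger RNA, so counts over the gene do not check the labels by themselves, and every direction below is drawn between libraries as labelled. In the authors' deposited table of UniGene clusters, the kctd10 fold was 1.4. The other adaptors of its family, tnfaip1 and kctd13, had log2 ratios of 0.19 and −0.42.

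Among genes with a symbol and at least 50 counts, the 12 farthest above no change in the library labelled mutant included vcana and has1, both matrix genes. The cytokine gene il11b and the complement genes c3b and c3c were also among them. The 12 farthest below included the muscle genes myhz2 and ankrd1b and the Hox genes hoxb13a, hoxc12a and hoxc12b. Clone names were left out of this ranking, and the clone-named BX323876.2 (39.8-fold higher, 31.8 to 50.4) lay beyond all 12 higher genes. Of 24009 genes with at least 10 counts, 1447 (6.03%) were higher, with the whole interval above 1.5-fold, and 1600 (6.66%) were lower by the same rule. The other 20962 met neither condition. The interval lay beyond 4-fold for 83 higher and 208 lower genes, and beyond 8-fold for 28 and 67. The split leaned to lower genes when all ratios were scaled to the cardiac sarcomere list, which gave 693 higher and 4355 lower genes, 13.7% higher among those called against 47.5%. That scaling was chosen after the data were seen and shifted every log2 ratio by −0.38.

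Among the 12 higher genes farthest from no change, vcana, which encodes the matrix proteoglycan versican, was 10.04-fold higher (9.64 to 10.5), with 2581 and 24458 counts. The hyaluronan synthase gene has1 was 13.7-fold higher (9.79 to 19.7) and the cytokine gene il11b 18.4-fold (11.97 to 29.7). The complement genes c3b and c3c were 12.8-fold (11.3 to 14.6) and 11.8-fold (11.1 to 12.6) higher, and C7 (2 of 2) was 21.0-fold higher (12.6 to 38.1). NPPC (1 of 2) and NPPC (2 of 2), named after C-type natriuretic peptide, were 12.6-fold and 16.9-fold higher. The remaining genes were plxdc1 (18.0-fold), mxtx1 (21.98-fold), tmem196b (13.8-fold) and PLA2G4C (1 of 5), whose ratio of 105 (28.7 to 872) rests on 2 against 198 counts. Genes named as copies, and the c3 genes, may share reads with near-identical relatives, so their single values are uncertain.

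Among the 12 lower genes, the muscle ankyrin repeat gene ankrd1b fell from 1019 to 6 counts, 160-fold lower (73.4 to 438). The fast skeletal myosin gene myhz2 had 24825 and 350 counts and was 67.0-fold lower (60.2 to 74.6). The muscle genes myhc4 and CKMT2 (2 of 2) were 29.4-fold and 30.1-fold lower, and cmn was 75.6-fold lower. The posterior Hox genes hoxb13a (241 and 4 counts) and hoxc12a (306 and 7 counts) were 56.9-fold and 41.3-fold lower. A paralogue, hoxc12b, had 121 and 0 counts and was at least 30.5-fold lower by its counting interval, which has no far end. Against a floor of 3 counts in the library labelled mutant it was 38.1-fold lower. kcnv2b, a potassium channel gene, had 141 and 1 counts, a ratio of 0.00751 (0.000189 to 0.0425). The transcription factor gene foxq2 had 429 and 2 counts, a ratio of 0.00494 (0.000596 to 0.0179), and the protocadherin gene pcdh8 was 28.4-fold lower.

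**Figure D1:**
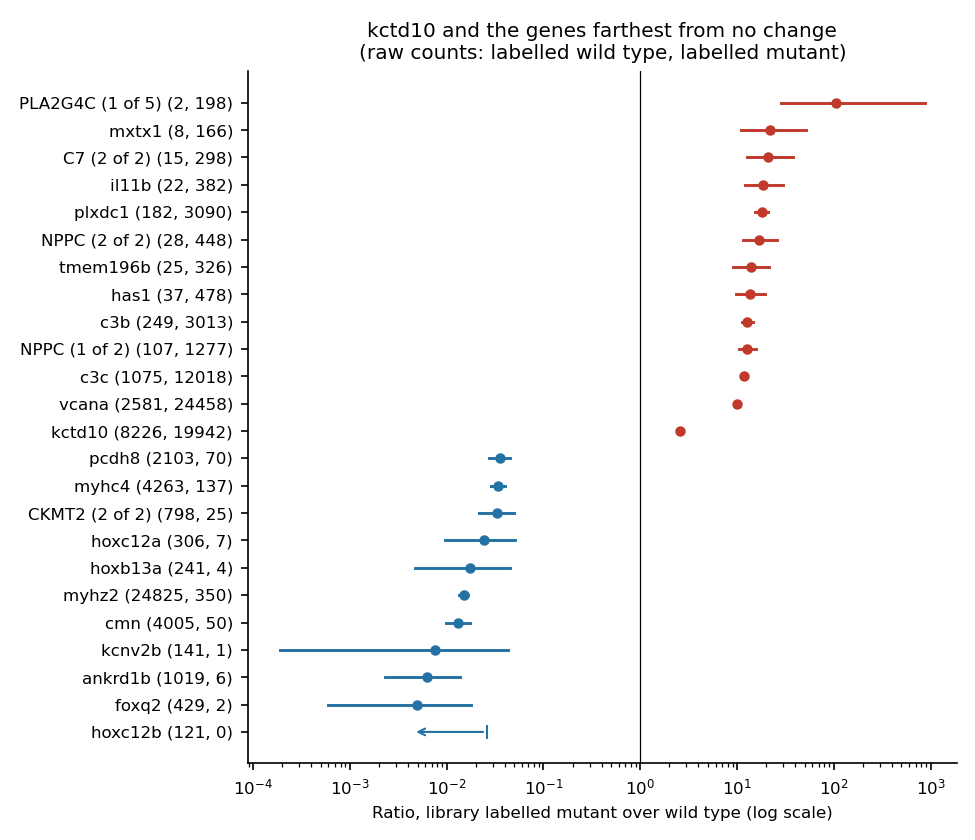
Ratio of the library labelled mutant over the library labelled wild type, on a log axis. Shown are kctd10 and the genes farthest from no change named in the text, among those with a symbol and at least 50 counts. Raw counts in both libraries stand beside each name. Points are ratios and bars 95% counting intervals of 1 library per genotype, red for higher and blue for lower, and the arrow for hoxc12b, with 0 counts in the library labelled mutant, starts at the floor of 3 counts. kctd10 lies at 2.57, vcana at 10.04 and myhz2 at 0.0149.

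The atrial and cardiac transcription factor lists lay above the random lists in the library labelled mutant, with medians of 0.50 and 0.49 against 0.38 for the sarcomere list, and the difference between atrial and ventricular lists was not tested. The atrial natriuretic peptide gene nppa was 2.55-fold higher (2.53 to 2.57) and the atrial myosin gene myh6 2.26-fold (2.23 to 2.28). Of 6 measured atrial markers 3 were higher and 0 lower. The median log2 ratio of the list was 0.50 (95% interval over members −0.096 to 1.35), at percentile 99.92 of 10000 random lists matched on expression. It was 0.12 when scaled to the sarcomere list. The 3 higher markers, nppa, myh6 and tbx5a, also stand in other lists reported here, so these lists are not separate evidence. Of 9 ventricular markers, hey2, a Notch-responsive repressor, was higher (2.19-fold) and irx4b was lower (4.16-fold), and the median of 0.13 (−0.66 to 0.58) lay at percentile 90.1, within the random lists, with a mean of −0.028 and a median of −0.25 under the sarcomere scaling. The ventricular myosin gene vmhc had a ratio of 1.49 (1.48 to 1.5). Among 20 cardiac transcription factor genes 7 were higher, among them hey2, mef2cb (2.13-fold), nkx2.5 (1.97-fold) and tbx5a (1.69-fold, 1.63 to 1.75). isl1, a gene of late-adding heart progenitors, was 1.78-fold lower, but the tissue that its counts came from was not measured. The median of that list was 0.49 (0.17 to 0.98), at percentile 100, and 0.11 under the sarcomere scaling.

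The lists of chamber differentiation, sarcomere and calcium handling genes held members that moved both ways. In the list of chamber differentiation and secreted natriuretic genes, BX323876.2, called nppal in the current name table, was 39.8-fold higher (31.8 to 50.4). ankrd1b and the methyltransferase gene smyd1a (5.39-fold) were lower. The list held 4 higher and 4 lower genes of 18, with a median of 0.43 at percentile 100, or 0.046 under the sarcomere scaling, and its mean of 0.18 lay at percentile 91.4. Of 31 sarcomere genes 10 were higher, including myh6, and 4 lower, including tcap (9.75-fold) and myoz2a (5.75-fold). The median of 0.38 (−0.055 to 0.67) lay at percentile 100 and the mean of 0.13 at 94.8. That median is 0 by construction under the sarcomere scaling. Of 20 calcium handling and ion channel genes 3 were higher, including jph2 (1.69-fold) and the sodium-calcium exchanger gene slc8a1a (1.64-fold), and 3 were lower, including slc8a1b (1.78-fold) and casq1b (2.62-fold). The median of that list was 0.25 at percentile 99.7, but −0.13 when scaled to the sarcomere list, and the mean lay at percentile 72.8. The median of the skeletal muscle list was −2.36 in the same libraries, and tcap, casq1b and smyd1a, lower members of these heart lists, are also known as skeletal muscle genes.

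The epicardial list, of genes of the outer layer of the heart, and the mixed list of outflow tract, second heart field and smooth muscle genes lay above the random lists in the library labelled mutant. The Wilms tumour genes wt1b and wt1a were 4.13-fold (3.67 to 4.67) and 3.46-fold (3.11 to 3.85) higher, and aldh1a2, which makes retinoic acid, 2.57-fold (2.49 to 2.65). Of 9 epicardial genes 5 were higher and 1, nell2b (1.88-fold), lower, with a median of 1.36 (−0.062 to 1.79) at percentile 100 and a mean of 0.81. Whether the counts of these genes came from the epicardium was not measured. The smooth muscle genes myh11a (4.87-fold, 4.57 to 5.20), tagln (3.37-fold) and acta2 (1.56-fold) were among 7 higher members of the 17 genes of the mixed list, where isl1 was the lower one. The median of this list was 0.35 (−0.24 to 0.98) at percentile 99.96, and −0.029 under the sarcomere scaling.

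The atrioventricular canal and endocardial cushion genes went both ways. Of 24, vcana and twist1b (2.18-fold) were higher and 5 were lower, including the flow-responsive gene klf2b (2.19-fold, 2.15 to 2.24) and spp1 (3.73-fold). The median of −0.03 lay at percentile 39.4, and the mean was 0.011. The canal genes bmp4 and has2, below the rule for higher genes, had ratios of 1.48 and 1.41. Of 27 endocardial and endothelial genes, cdh5 (1.90-fold) was higher, 3 were lower, including tek (1.79-fold) and aqp8a.1 (1.68-fold), and the median of −0.0048 lay at percentile 38.2, with a mean of 0.03 and a median of 0.021 when scaled to library totals. Among 38 matrix genes 9 were higher, led by has1 and vcana, and 6 lower, among them the collagen genes col2a1a (3.86-fold, 3.79 to 3.93) and col1a1a (1.84-fold) and postna (2.60-fold). col2a1a also stands in the cartilage, neural crest and pigment list, whose median was −0.37 in the same libraries. The matrix median of 0.12 lay at percentile 99.4 and was −0.26 under the sarcomere scaling.

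Signalling lists changed in a few members. Of 39 BMP, TGF-beta and Notch genes 7 were higher, including her15.1 (2.48-fold) and hey2, and 2 lower, id2b (2.03-fold) and bmpr2b (1.60-fold), with a median of 0.07 at percentile 89.6, which turned to −0.31 under the sarcomere scaling. The receptor gene notch3 had a ratio of 1.01. Of 29 Wnt genes the secreted antagonist genes sfrp5 (3.02-fold, 2.94 to 3.10) and dkk1b (2.45-fold) were among 3 higher, and the Wnt target sp5l (4.46-fold) and wnt4b (2.62-fold) among 4 lower, with a median of −0.07 at percentile 20.7.

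Genes of the stress and immediate early list were lower as a group in the library labelled mutant. ccng1, a cyclin gene outside that list, rose from 70678 to 245212 counts, 3.68-fold (3.64 to 3.71), and isg15 was 5.75-fold higher (3.59 to 9.65) on 21 and 114 counts. Of 39 stress and immediate early genes 20 were lower and 0 higher, led by fosb (21.0-fold, 19.8 to 22.2) and egr2a (10.2-fold, 9.19 to 11.4) and including gadd45ba (2.29-fold), with a median of −0.68 (−1.22 to −0.20) at percentile 0. The chaperone gene hsp90ab1 had a ratio of 0.901.

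The mitochondrially encoded and glycolysis lists lay above the random lists in the library labelled mutant. None of 37 cell cycle genes, 46 nuclear genes of the respiratory chain or 62 ribosomal protein genes was higher or lower. Their medians were −0.10, 0.07 and −0.10, at percentiles 4.32, 93.9 and 15.0, and the respiratory chain median turned to −0.31 under the sarcomere scaling. The cell cycle list fell below the random lists with at least 50 counts per gene (percentile 2.26), and the ribosomal list did so by its mean (percentile 1.15). Among the most counted members, MKI67, ATP5B and rpsa had ratios of 0.783, 0.890 and 0.978. The 13 mitochondrially encoded genes had a median of 0.48 (0.34 to 0.59) at percentile 100, or 0.096 under the sarcomere scaling, of which mt-co1 passed the rule (1.62-fold). Of 36 glycolysis and hypoxia genes 4 were higher, including igfbp1a (2.07-fold) and ldha (1.93-fold), and 2 lower, the muscle-type genes pkmb (4.74-fold) and pfkma (4.47-fold). That median was 0.16 at percentile 99.91, −0.22 under the sarcomere scaling, and the mean lay at percentile 77.2. gapdh had a ratio of 1.06.

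Markers of tissues other than the heart moved apart from each other between the libraries. Skeletal muscle genes were far lower, 32 of 40 by the rule, with a median of −2.36 (−2.67 to −1.80), a 5.14-fold lower level, at percentile 0. myhz1.3 was 16.7-fold lower and myf5, a gene of muscle precursors, 1.84-fold higher. acta1b, the most counted member, had a ratio of 0.862. Myeloid genes were higher, 17 of 23, with a median of 1.15 at percentile 100, including the scavenger receptor gene marco (7.68-fold, 5.86 to 10.2), si:ch211-122l24.4 (6.60-fold) and the lysozyme gene lyz (1.72-fold). Yolk and liver genes were higher in 26 of 41 cases with a median of 0.96 at percentile 100, including cfb (6.5-fold) and the apolipoprotein gene apobb (2.74-fold, 2.72 to 2.75). Of 27 erythrocyte genes 5 were higher, including rhag (1.94-fold) and epb41b (1.65-fold), and ank1 was lower (2.51-fold). That median of 0.19 lay at percentile 99.7 and turned to −0.19 under the sarcomere scaling, and hbae3 had a ratio of 0.926.

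The list of lens and retina genes lay above the random lists in the library labelled mutant, with members moving both ways, and the nervous system and neural crest lists lay below them. Of 43 lens and retina genes 20 were higher, including the lens fibre genes cx44.1 (5.35-fold), mipa (4.91-fold, 4.76 to 5.06) and crybb1 (2.83-fold), and 4 lower, including crx (10.3-fold, 9.78 to 10.9), a regulator of photoreceptor genes. The median was 0.62 at percentile 100. Nervous system genes were lower as a group, 9 lower and 2 higher of 43, with a median of −0.44 at percentile 0. otx2 (2.49-fold) and neurod (2.45-fold) were lower, foxg1a (1.91-fold) and dlx2b (1.94-fold) higher, and fabp7a had a ratio of 0.731. Cartilage, neural crest and pigment genes had 10 lower and 1 higher, twist1b, of 31, with a median of −0.37 at percentile 0. and1 and and2, structural genes of the larval fin fold, were 9.11-fold and 10.1-fold lower.

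The skin list lay below the random lists in the library labelled mutant, and the notochord and pharyngeal lists lay within them. Of 29 skin genes krt18 was higher (2.18-fold), krt15 (2.26-fold) and krt5 (1.81-fold) were lower, and the median of −0.22 lay at percentile 0.01. krt4 had a ratio of 0.700. Of 19 notochord, otic and hatching gland genes flh (3.07-fold) and cd63 (1.62-fold) were higher and 4 lower, including col8a1a (5.99-fold) and ctgfa (3.48-fold), and the median of −0.17 lay at percentile 4.13, the mean at 1.08. he1a had a ratio of 0.945. Of 27 pharyngeal, thyroid, gut and kidney genes nkx2.1b (2.94-fold) and foxa2 (1.61-fold) were higher and 3 lower, including the pancreatic hormone genes gcga (2.7-fold) and ins (2.20-fold), with a median of −0.04 at percentile 36.6 and a mean of 0.02. trpm7 had a ratio of 1.03. Of the 29 lists reported, 14 lay above and 5 below the random lists, against 1.45 by chance if members varied independently, which members of a pathway or tissue do not.

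**Figure D2:**
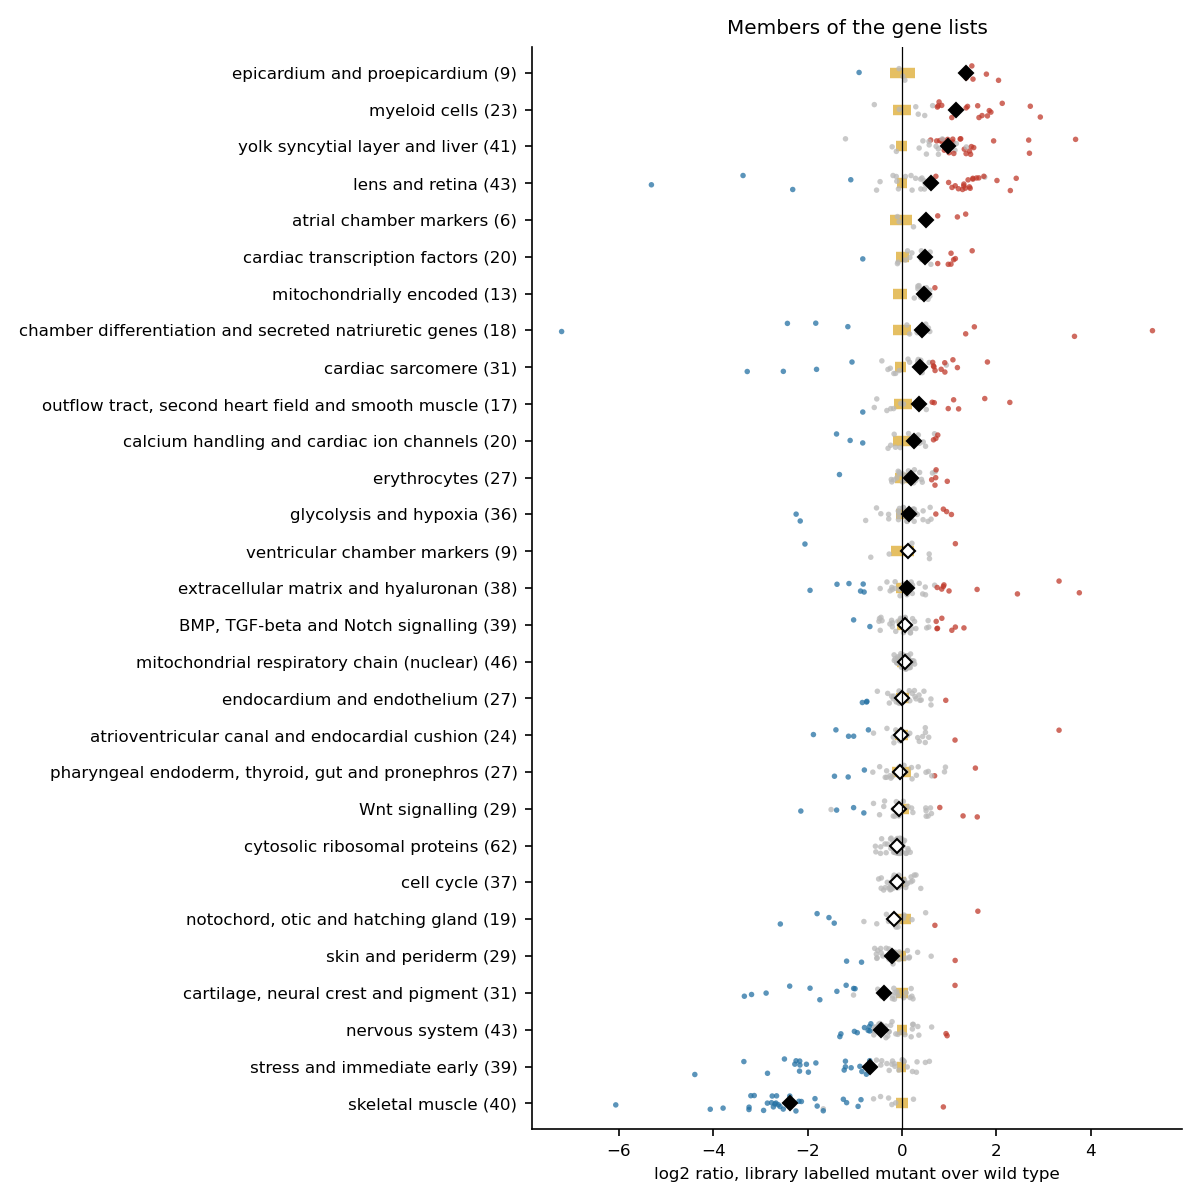
Each point is the log2 ratio, library labelled mutant over wild type, of 1 member of a gene list, red for higher, blue for lower and grey for neither, and each list is named with its number of measured members. Diamonds are list medians, filled where the list stands apart, and yellow bars hold the central 95% of medians of random lists matched on expression. Skeletal muscle lies lowest at a median of −2.36 and epicardium highest at 1.36.

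**Figure D3:**
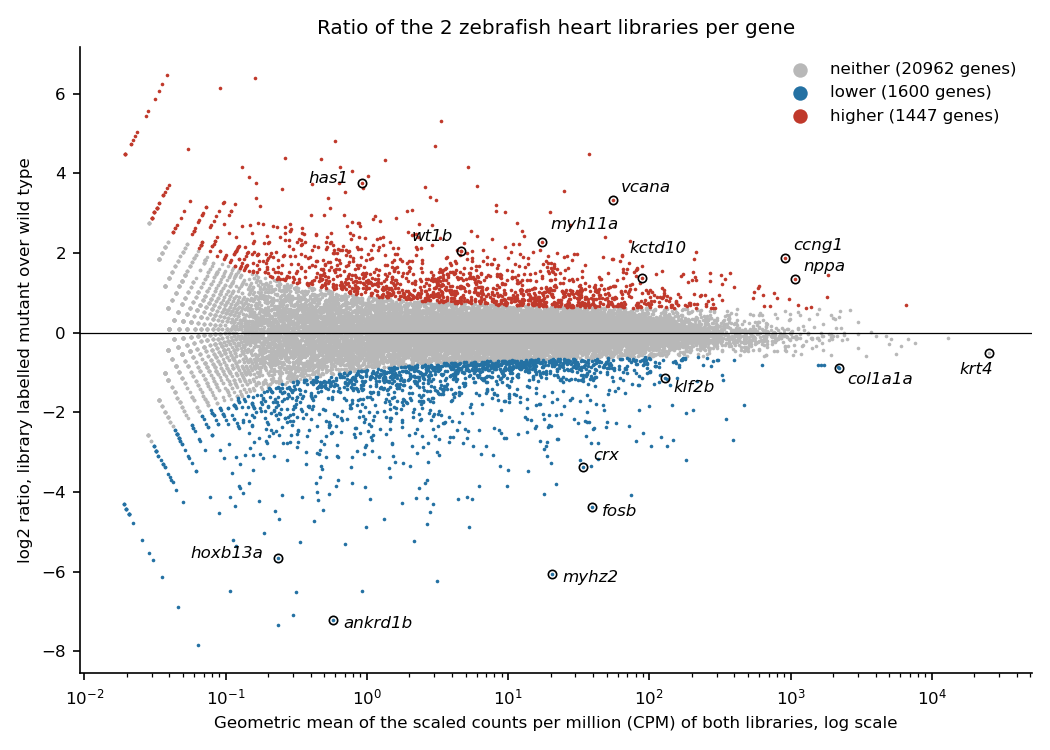
The log2 ratio of each measured gene against the geometric mean of its scaled level (CPM) in both libraries, on a log axis, with 1447 higher genes in red and 1600 lower genes in blue. Circles mark some of the genes named in the text, from has1 at 3.76 to ankrd1b at −7.21, and 0.5 was added to each count on this scale. krt4, at the right edge, has the most counts in both libraries.

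The authors' own comparisons were set beside these ratios. In the authors' deposited table of Ensembl genes, 442 genes had an adjusted p-value under 0.05 by DESeq, 187 higher and 255 lower, and all 442 were also called by the counting intervals. Both rest on the same counts of the same libraries, so a shared direction is given by construction and is no independent check. nppa, aldh1a2, wt1b, vcana and ccng1 were among its higher genes and myhz2, fosb, crx, and1 and col2a1a among its lower ones. For kctd10, the authors' deposited table gave a fold of 2.56 and an adjusted p-value of 0.043 by DESeq. That p-value was computed from 1 library per genotype, without replicates. Across 8233 symbols matched to the authors' deposited table of UniGene clusters, Pearson's r between both sets of log2 ratios was 0.979 across genes, which are not independent replicates, in a table of the same comparison. Of 488 matched higher genes 486 and of 519 matched lower genes 518 had the same sign in the authors' deposited table of clusters. kctd10 differed by −0.91 on the log2 scale between the authors' deposited table of clusters and the counts per Ensembl gene.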

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

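The scaling to the cardiac sarcomere list and the authors' folds for kctd10 were chosen after the data were seen, and the other alternatives before. With 2 libraries a scaling shifts all genes alike, so percentiles of lists do not depend on it. Size factors, library totals, upper-quartile factors and factors without the 100 most counted genes kept the higher and lower counts within 1.5 times of 1447 and 1600, kctd10 within its interval and all 29 list medians within theirs. So did filters at 50 counts or none and a stricter interval level for the counts. Requiring the interval beyond 2-fold gave 635 higher and 677 lower genes, and beyond 1 gave 8178 and 8188, as each limit is built to do. Scaling to the sarcomere list gave 693 higher and 4355 lower genes and a kctd10 ratio of 1.97. It turned the medians of the calcium and ion channel list to −0.13, outflow and smooth muscle to −0.029, extracellular matrix to −0.26, glycolysis to −0.22 and erythrocytes to −0.19. It also changed the sign of 3 medians that lay within the random lists, ventricular to −0.25, BMP, TGF-beta and Notch to −0.31 and nuclear respiratory chain to −0.31. Of the medians other than the first 5, 16 moved out of their interval and 8 did not. The construction shifts every median by −0.38, and what moved the sarcomere list itself was not tested. Of 118 named genes other than kctd10, 96 moved out of their own interval under it, against 26 under library totals and 21 under upper-quartile factors. The authors' UniGene fold for kctd10 was 1.4, and whether the gene model accounts for part of the difference is weighed among the other observations. With means in place of medians, 10 lists lay above and 7 below the random lists, against 14 and 5. The number of genes beyond 2-fold was 2872 by the computed ratio and by the authors' fold. Both use the same counts and differ by a constant log2 shift of −0.0052, so this is no independent check. Depth limited genes with few counts, such as spp1 (87 and 22 counts, interval 2.32-fold to 6.26-fold lower). No paired analysis was possible because each genotype has 1 library and the labels give no shared replicate number.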

Other observations

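The tests below, the gene sets they use and the genes named were chosen after the ratios were seen, except the test on caudal genes, which was fixed before its values were seen. Of 23 measured genes of paralogue groups 9 to 13, which pattern the trunk and tail, 21 were lower in the library labelled mutant and 0 higher, with a median log2 ratio of −2.40 (−3.30 to −1.73), a 5.28-fold lower level. hoxc13a (175 and 6 counts), hoxc11b (108 and 2 counts) and hoxa11b (504 and 88 counts) were among them. The median of the set does not depend on hoxc12b, at 0 in that library, which lies below the median at its bound too. Of 18 genes of groups 1 to 5, which pattern the hindbrain and pharynx, 1 was higher and 2 lower, with a median of −0.18 (−0.37 to 0.08), and 8 genes of groups 6 to 8 had a median of 0.11 (−0.96 to 1.14).

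Of 40 complement genes 30 were higher and 2 lower, with a median of 1.37 (1.06 to 1.94). Many are liver products, 4 stand in the yolk and liver list, and the medians of that list and of the myeloid list were 0.96 and 1.15 in the same direction. c3a was 4.07-fold higher, with 15681 and 60204 counts, c9 3.17-fold and c6 3.83-fold, and si:dkey-8k3.2 had 1169 and 24765 counts. The cytokine gene il11a (425 and 3341 counts) was 8.33-fold higher, beside its paralogue il11b. Photoreceptor genes had a median of −0.55 (−1.20 to −0.17) over 48 members, 18 lower and 1 higher, including the transcription regulator genes nr2e3 (8.53-fold lower), six7 (18.3-fold) and samd7 (17.6-fold), while 20 retinal progenitor genes had a median of 0.20. Of the 20 lower members of the stress list 14 belong to a set of immediate early genes assembled after those values were seen. The 29 genes of that set had 24 lower and a median of −1.82 (−2.27 to −1.13). A set of 27 heat shock and chaperone genes had a median of −0.12, with 5 lower and 0 higher. The 5 were hsp70l (4.74-fold), an identifier named mcm5 by the authors (4.47-fold), bag3 (1.86-fold), hsp90aa1.2 (1.86-fold) and dnajb1b (1.80-fold). The median near no change therefore does not describe every heat shock gene.

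kctd10 was 2.57-fold higher in the library labelled mutant. For the counts per Ensembl gene, the choice of scaling as the only cause is argued against by the smallest ratio over all scalings tried, 1.97. The scalings were not applied to the UniGene fold of 1.4, itself under the 1.5 of the rule. Scaling and gene model together were therefore not tested. The gene model on which reads were counted may account for part of the size, since the difference between the Ensembl and UniGene ratios of kctd10 was larger than for 99.7% of 8233 matched symbols, and both remained above 1. Exchanged labels cannot be told apart from a higher transcript in the mutant, because the ratio of 0.389 that an exchange would give is as possible as 2.57 without a second mark of the genotype. A rise of the mutated gene's own transcript through lost feedback stays open and was not tested.

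The skeletal muscle list, with 0 of its genes in another list, was 5.14-fold lower in the library labelled mutant, but its members moved apart, from myhz2 at −6.06 to myf5, which was higher, at 0.88, with acta1b, the most counted, at −0.21 (103329 and 84067 counts). A hypothesis is that less trunk and tail tissue was carried along with those hearts, though how many of these genes the heart itself expresses was not measured. Medians of Hox groups 9 to 13 and 1 to 5 differed by −2.22. However, 3 genes of the first set were already among the 12 lowest when it was chosen, so the difference lends no support. Groups 6 to 8 had a median above 0 (0.11, −0.96 to 1.14). A set of 11 caudal genes had a median of −0.47 at percentile 2.75, short of the limits of −0.5 and 2.5 fixed beforehand. Some of its members had few counts, such as cdx4 (28 and 13) and msgn1 (25 and 15), so this near miss does not decide the question. An earlier stage of those embryos could also lower late genes. The difference of −0.76 between photoreceptor and retinal progenitor medians, with intervals apart but under the size of 1 asked for, does not decide it. The photoreceptor set held kcnv2b, already among the 12 lowest, and the progenitor set held tbx5a, also listed as a cardiac gene. The lens and retina list went the other way, with a median of 0.62 and 20 higher and 4 lower of 43. An effect of the mutation on muscle and axis stays open.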
